A study of Homo sapiens with 15 samples.

How the data were processed

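The authors deposited one table of FPKM values, gene by library, for the 15 libraries, and this table was the only measurement used. Per the submitters' processing notes, reads were handled with Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 against GRCh38; the notes do not say which step each tool served, and the gene annotation is not given in the sources used here. Read counts and raw reads were not used here. FPKM were taken as deposited with no further scaling, and their fold changes were computed on log2(FPKM + 1), which understates the change of genes with low values. Columns were matched to conditions by the submitters' sample labels only.

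Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on genes with an FPKM of at least 1 in at least 3 libraries of the fit, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. The 9 AsPC-1 libraries were fitted together, the 6 Capan-1 libraries apart, and the difference between lines in the response to B3GNT3 knockdown was the interaction in a fit of all 15. In the comparison of both knockdowns in AsPC-1 the siNC libraries enter only through the estimate of spread. In that of siB4GALT5 with siNC the siB3GNT3 libraries, the one labelled replicate 3 included, enter standard errors and p-values in the same way. Values after ± are SDs of FPKM over the 3 libraries of a group, and log2 fold changes are given with their standard errors where space allows.

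Gene lists were tested with camera from limma with its preset correlation of 0.01, and again with the correlation estimated from the data; p-values were adjusted over the lists of a comparison, and lists with fewer than 3 genes past the filter were not tested. The 32 lists were written from general knowledge before the data were examined; of 699 names 682 were found in the table, 24 of them under another symbol. Tests, thresholds, lists, the rule for naming genes and most alternatives were also fixed before the data were examined. That rule names both targets, every MHC class I chain, up to 4 members of each other list with the smallest p, and up to 8 genes per direction with the largest changes (5 in the comparison of both knockdowns and in the interaction). Genes of the last kind had an adjusted p under 0.05, all 3 knockdown libraries beyond all 3 controls and a mean of at least 5 FPKM in one group. Not every gene this rule picks is described. For B3GNT3 knockdown in AsPC-1, where no gene was called, the rule was applied without the library labelled AsPC-1 siB3GNT3 replicate 3, a step added after the data were seen.

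Alternatives tried were pseudocount 0.1, no filter and a stricter filter of 5 FPKM, median-ratio scaling, rescaling to a common sum, no intensity trend, the replicate number as a block, each library left out in turn, fits of fewer or more groups, and an added threshold of 2-fold. Added after the data were seen were list tests, named genes and agreement without the library labelled AsPC-1 siB3GNT3 replicate 3, lists without Capan-1 siB3GNT3 replicate 3, lists under the other scalings, the MHC class I and interferon lists under each alternative with an estimated correlation, counts without the 13 mitochondrially encoded mRNAs, and agreement with each library left out. Agreement between comparisons was measured by Pearson r and covariance across genes. For the knockdowns that share controls it was set against 100 simulations of unchanged groups that share them.

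A scan for seed matches, added after the changes in expression had been seen, scored each of the 16384 possible 7-mers by how far genes with it in the longest 3' UTR (GENCODE 29) lay below other genes, after regression on UTR length and GC content; 7-mers in fewer than 50 genes were not scored, and the bound for all 7-mers was -4.523. The scan ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

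The tests were tested on simulated data. With 200 genes changed in all 3 libraries of a group, 94.0% of 1.5-fold and 93.9% of 4-fold changes were recovered for B4GALT5 in AsPC-1, and 91.0% of 1.5-fold and 95.5% of 2-fold changes in Capan-1. The simulated spread came from the siNC libraries, which within a line had root mean square log2 differences of 0.135 to 0.147. Libraries of siB4GALT5 differed by 0.151 to 0.271 and those of Capan-1 siB3GNT3 by 0.177 to 0.314, so recovery may be overstated. For B4GALT5 the simulated spread also lacked what the library labelled AsPC-1 siB3GNT3 replicate 3 adds to the real fit. With the change in replicates 1 and 2 only, as the library labelled AsPC-1 siB3GNT3 replicate 3 leaves it, 1 of 66 4-fold changes was recovered and none of the smaller ones. A planted shift of 0.5 in a list of 30 genes was called in 20 of 20 runs with either correlation, and an unchanged list in 0. Noise was drawn for each gene apart, so these runs do not show how the test does when genes are correlated. A planted 7-mer scored lowest in 10 of 10 runs, while permuted values reached -4.664, slightly past the bound.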

Results

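Expression was measured by RNA sequencing in 15 libraries from 2 human pancreatic ductal adenocarcinoma cell lines, AsPC-1 and Capan-1, in 5 groups of 3 libraries. AsPC-1 cells had received a control siRNA (siNC), an siRNA against B4GALT5 or an siRNA against B3GNT3. Capan-1 cells had received siNC or an siRNA against B3GNT3. B4GALT5 encodes a Golgi galactosyltransferase that makes lactosylceramide, and B3GNT3 encodes an N-acetylglucosaminyltransferase that extends core 1 O-glycans. The series asks whether loss of either enzyme changes MHC class I and with it the response of CD8 T cells; these data measure mRNA, not protein at the cell surface.

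The values were FPKM for 25503 genes, of which 988 were listed at 0 in every library. Read depth is unknown, since FPKM carry no counts, so no counting interval or detection floor is given. Between 10339 and 11531 genes per library reached an FPKM of 1. The mitochondrially encoded COX1 was the most abundant gene in each library. Mitochondrially encoded mRNAs made up 23.8% to 24.8% of FPKM in AsPC-1 siNC and 13.6% to 14.8% in the Capan-1 libraries. No label states that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries only.

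B4GALT5 (chromosome 20, 49632945 to 49713878, minus strand, GRCh38) was far lower in each library of its knockdown group. It was 38.7, 35.8 and 35.5 FPKM in AsPC-1 siNC and 8.71, 8.49 and 8.03 FPKM with siB4GALT5. The means were 36.7 ± 1.74 and 8.41 ± 0.343 (SD, n = 3), a fall by 2.00 on the log2 scale (limma, SE 0.07, adjusted p = 2.44e-06). B3GNT3 (chromosome 19, 17794828 to 17813082, plus strand, GRCh38) was 22.5, 23.8 and 23.3 FPKM in AsPC-1 siNC. With siB3GNT3 it was 2.53 and 2.50 FPKM in replicates 1 and 2, but 24.2 FPKM in the library labelled AsPC-1 siB3GNT3 replicate 3. The group mean was 9.73 ± 12.5 (SD, n = 3), with a log2 fold change of -1.83 (SE 0.63, adjusted p = 0.168). Without that library B3GNT3 fell by 2.78 (adjusted p = 6.67e-08), a value that is circular, since the library was singled out by this gene. In Capan-1, B3GNT3 was 13.3, 13.2 and 13.7 FPKM with siNC and 1.32, 1.67 and 1.84 FPKM with siB3GNT3. Its means were 13.4 ± 0.253 and 1.61 ± 0.264 (SD, n = 3), and it fell by 2.47 (SE 0.09, adjusted p = 1.23e-05). B4GALT5 was 35.0 ± 1.62 FPKM with siB3GNT3 in AsPC-1 (adjusted p = 0.548). In Capan-1 it was 68.2 ± 4.42 against 75.5 ± 1.16 FPKM in siNC (adjusted p = 0.12).

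**Figure D1:**
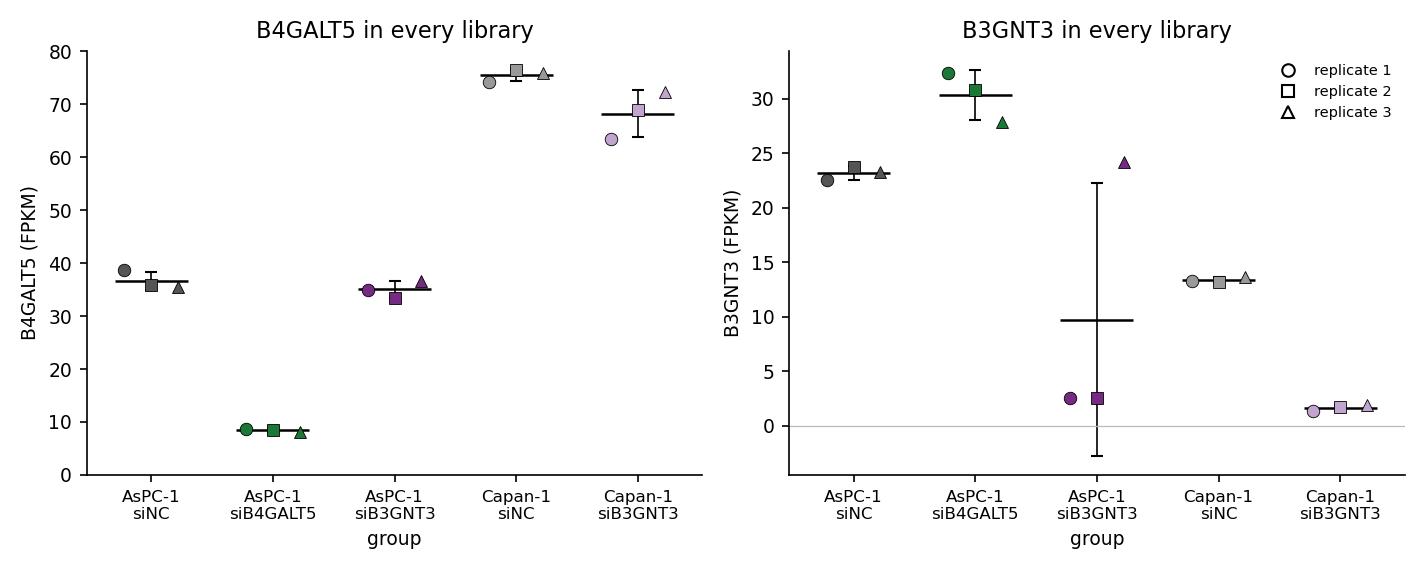
B4GALT5 and B3GNT3 in FPKM in each of the 15 libraries by group; points are libraries, horizontal lines group means and error bars 1 SD (n = 3). B3GNT3 was 24.2 FPKM in the library labelled AsPC-1 siB3GNT3 replicate 3, against 2.53 and 2.50 FPKM in replicates 1 and 2.

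The library labelled AsPC-1 siB3GNT3 replicate 3 resembled the controls in other genes too. Its root mean square log2 difference was 0.141 to 0.150 from the 3 siNC libraries and 0.475 to 0.489 from replicates 1 and 2 of its own group. The siNC libraries differed from each other by 0.143 to 0.147. Tested alone against the 3 siNC libraries with limma, it differed in 0 of 10804 genes at an adjusted p under 0.05 and in 169 at an unadjusted p under 0.05, with the spread taken from the other libraries of the fit. The same test of 1 library against 3, run after this was seen and without the doubted library, called 4094 and 4338 genes for siB3GNT3 replicates 1 and 2, and 4450, 5055 and 5841 for siB4GALT5 replicates 1, 2 and 3. Mitochondrial mRNAs made up 24.3% of its FPKM, against 20.1% and 19.8% in replicates 1 and 2 of its group. By its B3GNT3 level and its distances from the other libraries, its label is in doubt.

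Knockdown of B4GALT5 in AsPC-1 raised interferon-stimulated genes more than any other of the 26 gene lists tested in this line, by median. RSAD2, which encodes the antiviral protein viperin, went from 1.20 ± 0.167 to 24.1 ± 6.12 FPKM (mean ± SD, n = 3; log2 fold change 3.48, SE 0.58, adjusted p = 0.00347). IFIT2, which binds foreign RNA, went from 16.8 ± 0.554 to 153 ± 29.1 FPKM (3.09, SE 0.49, adjusted p = 0.0029). IFI6 rose by 2.95 and IFI27 by 4.01, from 0.851 ± 0.254 to 32.0 ± 16.7 FPKM (adjusted p = 0.00508 and 0.0105). IFNL1, the gene of interferon lambda 1, rose from 0.152 ± 0.114 to 7.69 ± 2.43 FPKM (adjusted p = 0.00399). Of the 39 interferon-stimulated genes tested, 35 rose and 0 fell, with a median of 1.57 (camera adjusted p = 1.07e-10, and 0.52 with an estimated correlation). HERC6, OAS2 and PLSCR1 were among them (1.97, 2.58 and 1.41).

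Genes of the amino acid stress response rose as well. PPP1R15A, the phosphatase subunit that ends this response, went from 14.3 ± 0.144 to 133 ± 25.7 FPKM (3.11, SE 0.63, adjusted p = 0.00678). DDIT3, its proapoptotic transcription factor CHOP, went from 16.1 ± 1.45 to 133 ± 22.1 FPKM (2.96, adjusted p = 0.00847). SESN2 rose by 2.35 and DDIT4 by 1.54. In the ATF4 list 13 of 20 genes rose and 0 fell (median 0.87, camera adjusted p = 0.000249, and 0.646 with an estimated correlation). Of the NF-kB targets 8 of 14 rose and 0 fell, TNIP1 by 1.15 and NFKB2 by 1.17 (median 0.66, adjusted p = 0.00169, and 0.52 with an estimated correlation). Among chemokines and cytokines 4 of 14 rose and 0 fell, including CCL5 by 2.35, IL1A by 2.29 and CXCL8 by 1.72 (median 0.57, adjusted p = 0.048, and 0.674 with an estimated correlation). KRT17, a basal keratin whose reads are shared with near-identical copies, went from 6.93 ± 0.842 to 70.7 ± 6.33 FPKM (3.18, adjusted p = 0.00387).

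MHC class I mRNA rose moderately. HLA-E rose from 40.3 ± 0.988 FPKM in siNC to 58.1 ± 4.17 with siB4GALT5 (log2 fold change 0.51, SE 0.10, adjusted p = 0.00602). HLA-B was 60.8 ± 5.35 and 90.8 ± 15.3 FPKM (0.56, adjusted p = 0.0277), and B2M, the shared light chain, 251 ± 11.6 and 321 ± 37.5 FPKM (0.35, adjusted p = 0.0186). HLA-C and HLA-F had log2 fold changes of 0.11 and -0.29 (adjusted p = 0.321 and 0.0941). HLA genes share reads with each other, so the split of their FPKM is uncertain. Some of these calls were lost when a single library was left out. HLA-B lost its call without siNC replicate 1, siNC replicate 2, siB4GALT5 replicate 1 or siB4GALT5 replicate 2 (adjusted p = 0.0865, 0.0865, 0.0659 and 0.0979). B2M lost it without siNC replicate 1, siNC replicate 2 or siB4GALT5 replicate 2 (0.0664, 0.0659 and 0.058). Each of these fits kept the library labelled AsPC-1 siB3GNT3 replicate 3, which enters the estimate of spread. Over all libraries left out in turn, HLA-B ranged from 0.44 to 0.67 (limma adjusted p = 0.00168 to 0.0979). B2M ranged from 0.25 to 0.40 (limma adjusted p = 0.00426 to 0.0664). HLA-F fell without the library labelled AsPC-1 siB3GNT3 replicate 3 (-0.29, adjusted p = 0.0321) and with median-ratio scaling (-0.34, adjusted p = 0.0407). In all, 4 of 6 chains rose and 0 fell (median 0.43, camera adjusted p = 0.202). Of the peptide processing genes 4 of 15 rose and 2 fell: the peptide transporter TAP1 rose by 0.88 and the immunoproteasome subunit PSMB8 by 0.52, while PSMB10 fell by 0.41 and CALR by 0.47 (median 0.14, adjusted p = 0.569). Of the genes of MHC class I turnover 5 of 15 rose and 0 fell, among them the autophagy receptor SQSTM1 by 0.98 and the ubiquitin ligase SYVN1 by 0.75 (median 0.19, adjusted p = 0.289).

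Other genes fell after B4GALT5 knockdown. EBPL, a sterol isomerase relative, went from 42.6 ± 3.13 to 4.32 ± 0.926 FPKM (mean ± SD, n = 3; -3.05, SE 0.15, adjusted p = 1.27e-05). The cargo receptor LMAN2 went from 142 ± 1.27 to 24.9 ± 3.36 FPKM (-2.47, adjusted p = 2.44e-06). The glycine cleavage subunit GCSH went from 35.3 ± 2.23 to 6.21 ± 0.686 FPKM (-2.33, adjusted p = 1.27e-05). The peroxidase PRDX1 went from 672 ± 20.1 to 171 ± 25.4 FPKM (-1.98, adjusted p = 0.00129). The transcription factor FOXS1, the microtubule regulator DPYSL2 and the desaturase SCD fell by 2.24, 1.93 and 1.69 (adjusted p = 0.000331, 1.27e-05 and 0.00217). Cholesterol synthesis genes fell, 11 of 23, with LSS falling by 1.11 and FDPS by 0.60, while 1 rose (median -0.56, camera adjusted p = 0.000273, and 0.52 with an estimated correlation). Of 34 cell cycle genes 17 fell and 0 rose, FOXM1 by 0.85 and TOP2A by 0.78 (median -0.40, adjusted p = 5.52e-07, and 0.52 with an estimated correlation). Mitochondrially encoded mRNAs fell, 10 of 13, COX1 by 0.50 and ND4 by 0.51 (median -0.51, adjusted p = 3.94e-05, and 0.52 with an estimated correlation).

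Markers of tumour subtype moved too. Of 12 mesenchymal genes 8 rose and 2 fell, SNAI2 rising by 0.84 and MMP14 by 0.82 (median 0.61, camera adjusted p = 0.0315, and 0.52 with an estimated correlation). Of 8 classical genes 3 fell and 0 rose: TSPAN8 by 1.02, HNF4A by 0.73 and LGALS4 by 1.11 (median -0.33, adjusted p = 0.048, and 0.52 with an estimated correlation). Without the library labelled AsPC-1 siB3GNT3 replicate 3, both calls ended (adjusted p = 0.0557 and 0.0574) and one was gained, EGFR and MAPK output (adjusted p = 0.0265, and 0.28 with an estimated correlation). That list had 11 of 19 genes up and 2 down with all libraries, SPRY2 by 1.60 and EGR1 by 1.38 (median 0.41, adjusted p = 0.0529). Of hypoxia and glycolysis genes 10 of 27 fell and 5 rose, ALDOC falling by 1.33 and BNIP3L rising by 0.69 (median -0.23, adjusted p = 0.048, and 0.539 with an estimated correlation). Basal-like genes had 2 of 10 up, KRT17 and AREG, and 1 down, KRT5 by 1.18, with a median of -0.04 that changed sign with the scaling and a mean of 0.28 (adjusted p = 0.578, direction down). Epithelial genes had 4 of 9 up and 1 down, KRT18 rising and KRT8 falling by 0.52 (median 0.07, adjusted p = 0.661).

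The other lists had no call in this comparison. In the families of both targets 4 of 13 rose and 2 fell; B4GALT1, a paralogue of B4GALT5, went from 20.1 ± 1.06 to 74.0 ± 0.4 FPKM (1.83, SE 0.41, adjusted p = 0.0094; list median 0.17, though camera pointed down, adjusted p = 0.956). The SE of B4GALT1 is wide beside these SDs because it also holds the spread of the siB3GNT3 group. B3GNT3 was 30.3 ± 2.29 FPKM (0.37, adjusted p = 0.657), and without the library labelled AsPC-1 siB3GNT3 replicate 3 it rose (0.37, adjusted p = 0.000892). Glycosphingolipid synthesis had 6 of 20 down, B4GALT5 and GAL3ST1 among them, and 1 up (median -0.14, adjusted p = 0.0529). Replicate 3 of siB4GALT5 stood apart in SPTLC1 and GLTP of this list, at 20.8 and 32.7 FPKM against 7.14 and 6.14 in replicate 1 and 7.18 and 5.72 in replicate 2. Its root mean square log2 differences from those were 0.251 and 0.271, and they differed by 0.151. O-glycan synthesis had 3 of 15 down and 1 up, ST3GAL1 by 0.70 (median -0.09, adjusted p = 0.468). Lysosome genes had 13 of 35 up and 2 down, CTSB rising by 0.49 (median 0.13, adjusted p = 0.0891). ER chaperone genes had 7 of 22 up and 2 down, DNAJB9 rising by 1.55 and CALR falling (median 0.18, adjusted p = 0.542). Ligands of T and NK cells had 5 of 18 up and 3 down, ULBP1 rising by 0.91 and HHLA2 falling by 1.06 (median 0.16, adjusted p = 0.844). The p53 targets had 5 of 17 up and 0 down, CDKN1A by 0.97 (median 0.23, adjusted p = 0.13). YAP targets had 4 of 14 up and 1 down, LATS2 rising by 1.64 and CCN1 by 1.06 (median 0.17, adjusted p = 0.217). Ribosomal protein genes had 5 of 34 up and 1 down, RPL11 rising by 0.43 and RPL23 falling by 0.36 (median 0.09, adjusted p = 0.553). Histone genes, which share reads with near-identical copies, had 2 of 9 up, H1-2 by 1.16 (median 0.46, adjusted p = 0.12).

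In total 4239 of 10804 genes changed with B4GALT5 knockdown, 2609 up and 1630 down, and 434 of them at least 2-fold (322 up, 112 down). In each gene named here as changed, the 3 knockdown libraries lay on one side of the 3 controls. Chance gives this for 10% of genes, and for the largest changes the naming rule required it. Some list calls depended on the scaling as well. Chemokines and cytokines lost theirs with rescaling to a common sum (camera adjusted p = 0.0807), classical and hypoxia genes with median-ratio scaling (0.066 and 0.0768), and mesenchymal genes with either (0.304 and 0.0677). EGFR and MAPK output gained one with rescaling to a common sum (0.0267, and 0.639 with an estimated correlation). The balance of directions of single genes shifted too: 2159 rose and 2027 fell with median-ratio scaling, and 3288 rose and 1259 fell with rescaling to a common sum. These moved the median of all genes from 0.06 to -0.01 and 0.15. Adjusted over the list alone, the counts differed from those above in 10 lists: 37 interferon-stimulated genes, 9 NF-kB targets, 16 ATF4 genes, 4 p53 targets and 1 basal-like gene rose, and 13 cholesterol, 19 cell cycle, 11 hypoxia and 11 mitochondrial genes fell, while EGFR and MAPK output had 12 up. The count of changed genes fell to 2475, 2441 and 2439 without siNC replicates 1, 2 and 3, and to 2595, 2596 and 3727 without siB4GALT5 replicates 1, 2 and 3. It rose to 6271 of 10775 without the library labelled AsPC-1 siB3GNT3 replicate 3. That library is in neither group compared but enters the estimate of spread. Simulated changes in this comparison were drawn with the spread of the siNC libraries. Of 67 genes with 1.5-fold changes 63 were recovered, with 11 false calls among 10547 genes tested. The siB3GNT3 libraries were drawn alike in these runs. The spread that the library labelled AsPC-1 siB3GNT3 replicate 3 adds to the real fit was thus missing, so recovery may be overstated.

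**Figure D2:**
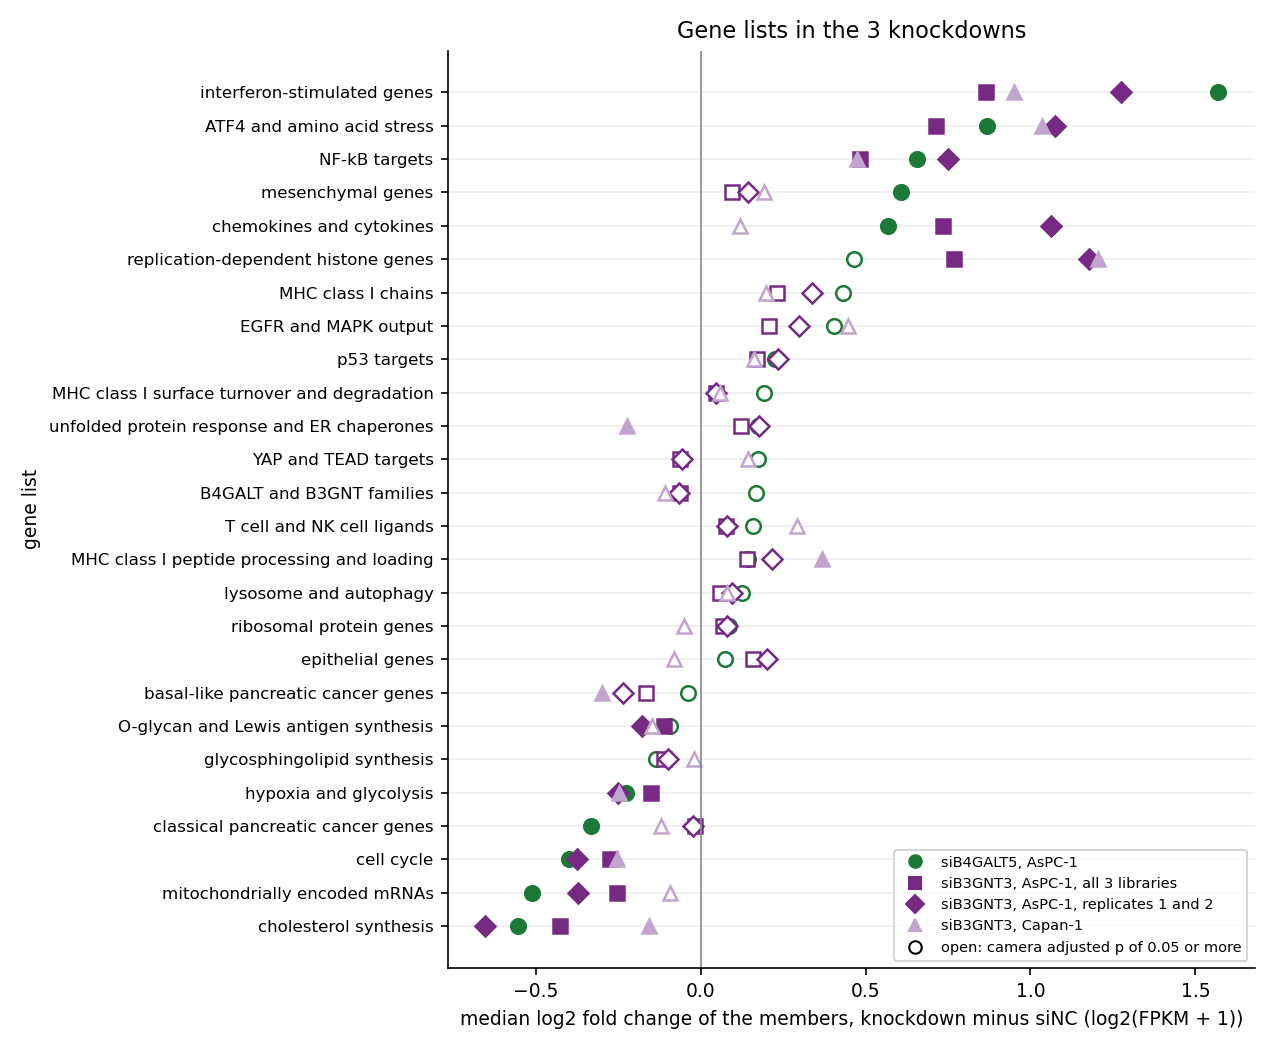
Median log2 fold change of each gene list (log2(FPKM + 1), knockdown minus siNC) for the lists tested in AsPC-1, in the 3 knockdowns and, for siB3GNT3 in AsPC-1, also in replicates 1 and 2 alone; filled points have a camera adjusted p under 0.05. Interferon-stimulated genes had medians of 1.57 with siB4GALT5 in AsPC-1 and 0.95 with siB3GNT3 in Capan-1; small medians can change sign with the scaling, as for basal-like genes with siB4GALT5.

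Knockdown of B3GNT3 in AsPC-1 gave no call on single genes with all libraries: limma called 0 of 10804 genes at an adjusted p under 0.05, and 3011 had an unadjusted p under 0.05. Without the library labelled AsPC-1 siB3GNT3 replicate 3, 5697 of 10775 genes changed, 3504 up and 2193 down, of which 435 at least 2-fold (308 up, 127 down). Simulated changes placed in replicates 1 and 2 only gave 0 calls among 10597 genes, and in all 3 replicates 7646 among 10775. Leaving out any other of the AsPC-1 libraries left the count at 0. The values below come from replicates 1 and 2 against the 3 siNC libraries, a choice made after the data were seen. Those replicates were kept because the target was low in them, so the p-values below describe the kept libraries and do not test the group as labelled. With all libraries nearly every gene named had an adjusted p of 0.168, and none was under 0.05.

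In those replicates the same stress and interferon genes were high as after B4GALT5 knockdown. GDF15, a stress cytokine, averaged 24.0 FPKM against 2.06 ± 0.216 in siNC (SD, n = 3; log2 fold change 3.03, adjusted p = 2.87e-07). DDIT3 averaged 114.7 FPKM against 16.1 ± 1.45 (2.76, adjusted p = 7.22e-07). PPP1R15A, TRIB3 and SESN2 rose by 2.84, 2.45 and 2.05. In the ATF4 list 19 of 20 rose and 0 fell (median 1.07, camera adjusted p = 6.37e-10, and 0.167 with an estimated correlation; with all libraries 0.72 and 3.09e-06, and 0.561 with an estimated correlation). IFI27, IFI6 and RSAD2 rose by 4.17, 2.79 and 2.75, and the RNA sensor IFIH1 by 1.92. Of 39 interferon-stimulated genes 36 rose and 0 fell (median 1.27, adjusted p = 1.33e-12, and 0.238 with an estimated correlation; with all libraries 0.86 and 1.01e-09, and 0.561 with an estimated correlation). The EGFR ligand AREG averaged 66.7 FPKM against 9.81 ± 0.653 (2.65, adjusted p = 2.53e-06). KRT17 rose by 2.52. CCL5, CXCL8 and IL1A rose by 1.90, 1.93 and 2.09 among 11 of 14 chemokines and cytokines (median 1.06, adjusted p = 0.000179, and 0.118 with an estimated correlation). RELB rose by 1.77 among 11 of 14 NF-kB targets, with 1 down (median 0.75, adjusted p = 0.00135, and 0.238 with an estimated correlation).

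MHC class I mRNA was higher in replicates 1 and 2 as well. HLA-B rose by 0.57, HLA-C by 0.19, HLA-E by 0.34 and HLA-F by 0.33 (adjusted p = 0.00336, 0.0432, 0.00192 and 0.03). B2M averaged 281 FPKM against 251 ± 11.6 in siNC (SD, n = 3; 0.16, adjusted p = 0.145). With all libraries the adjusted p-values of HLA-B, HLA-C, HLA-E, HLA-F and B2M were 0.178, 0.324, 0.177, 0.233 and 0.425. The list median was 0.34 (camera adjusted p = 0.112), and with all libraries 0.23 (0.0776). Without siNC replicate 3 and with the other libraries kept, the list passed (median 0.29, adjusted p = 0.0329, and 0.548 with an estimated correlation). TAP1 rose by 0.70, PSMB8 by 0.36 and the trimming peptidase ERAP1 by 0.89 among 7 of 15 processing genes, with 0 down (median 0.22, adjusted p = 0.326; 0.14 with all libraries). Genes of MHC class I turnover had 7 of 15 up and 4 down, MAP1LC3B rising by 0.79, with a median of 0.05 that changed sign with the scaling (adjusted p = 0.889).

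The largest fall besides B3GNT3 was in EEF1A1, the translation elongation factor, which averaged 190.5 FPKM against 1109 ± 19.97 in siNC (SD, n = 3; -2.54, adjusted p = 2.85e-09); reads of EEF1A1 are shared with near-identical copies. RDH11, RALB, TACC1 and SIGIRR fell by 2.27, 2.02, 1.97 and 1.91. Of 23 genes of cholesterol synthesis 17 fell and 1 rose (median -0.65, camera adjusted p = 6.59e-08, and 0.118 with an estimated correlation). RRM2 fell by 1.48 and CCNB1 by 0.82 among 23 of 34 cell cycle genes, with 1 up (median -0.37, adjusted p = 2.3e-08, and 0.333 with an estimated correlation). Mitochondrially encoded mRNAs fell, 12 of 13 (median -0.37, adjusted p = 3.98e-05, and 0.238 with an estimated correlation). Hypoxia and glycolysis genes had 15 of 27 down and 3 up, PKM falling by 0.76 and VEGFA rising by 1.88 (median -0.25, adjusted p = 0.00442, and 0.238 with an estimated correlation). O-glycan synthesis had 6 of 15 down and 1 up, B3GNT3 and ST3GAL4 falling (median -0.18, adjusted p = 0.00482, and 0.167 with an estimated correlation). That list holds the target itself, for whose low level these libraries were kept, and it was not tested without B3GNT3. Histone genes had 7 of 9 up, H2BC5 by 1.98 and H1-2 by 1.46 (median 1.18, adjusted p = 0.00222, and 0.466 with an estimated correlation).

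The remaining lists had no camera call for B3GNT3 in AsPC-1 without that library. Glycosphingolipid synthesis had 6 of 20 down and 3 up, B4GALNT1 falling by 1.46 (median -0.10, adjusted p = 0.106). ER chaperone genes had 11 of 22 up and 4 down, XBP1 rising by 1.50 and HSPA5 by 0.81 (median 0.18, adjusted p = 0.347). The p53 targets had 9 of 17 up and 3 down (median 0.23, adjusted p = 0.492), EGFR and MAPK output 9 of 19 up and 4 down (0.30, adjusted p = 0.326), and mesenchymal genes 4 of 12 up and 2 down (0.14, adjusted p = 0.711). Epithelial genes had 5 of 9 up and 2 down, KRT19 and KRT8 falling (median 0.20, adjusted p = 0.681). Basal-like genes had 3 of 10 up and 5 down, with a median of -0.24 and a mean of 0.25 (adjusted p = 0.346). In another 6 lists the median changed sign with the scaling, so no direction is given: 8 of 13 genes in the families of both targets changed, 8 of 18 ligands of T and NK cells, 6 of 14 YAP targets, 4 of 8 classical genes, 15 of 35 lysosome genes and 16 of 34 ribosomal protein genes. B4GALT1, in the first of these lists, averaged 71.9 FPKM against 20.1 ± 1.06 in siNC (SD, n = 3; 1.79, adjusted p = 1.05e-07). Median-ratio scaling gave 2644 genes up and 3024 down without that library, and rescaling to a common sum 4626 up and 1733 down. Adjusted over the list alone, 35 interferon-stimulated genes, 14 ATF4 genes, 5 histone genes, 2 NF-kB targets, 1 p53 target and 1 mesenchymal gene rose with all libraries. Without that library the counts adjusted over the list alone differed in 7 lists: 12 NF-kB targets, 10 genes of EGFR and MAPK output, 4 hypoxia genes, 2 classical genes and 2 cholesterol genes rose, and 25 cell cycle, 19 cholesterol and 6 basal-like genes fell.

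**Figure D3:**
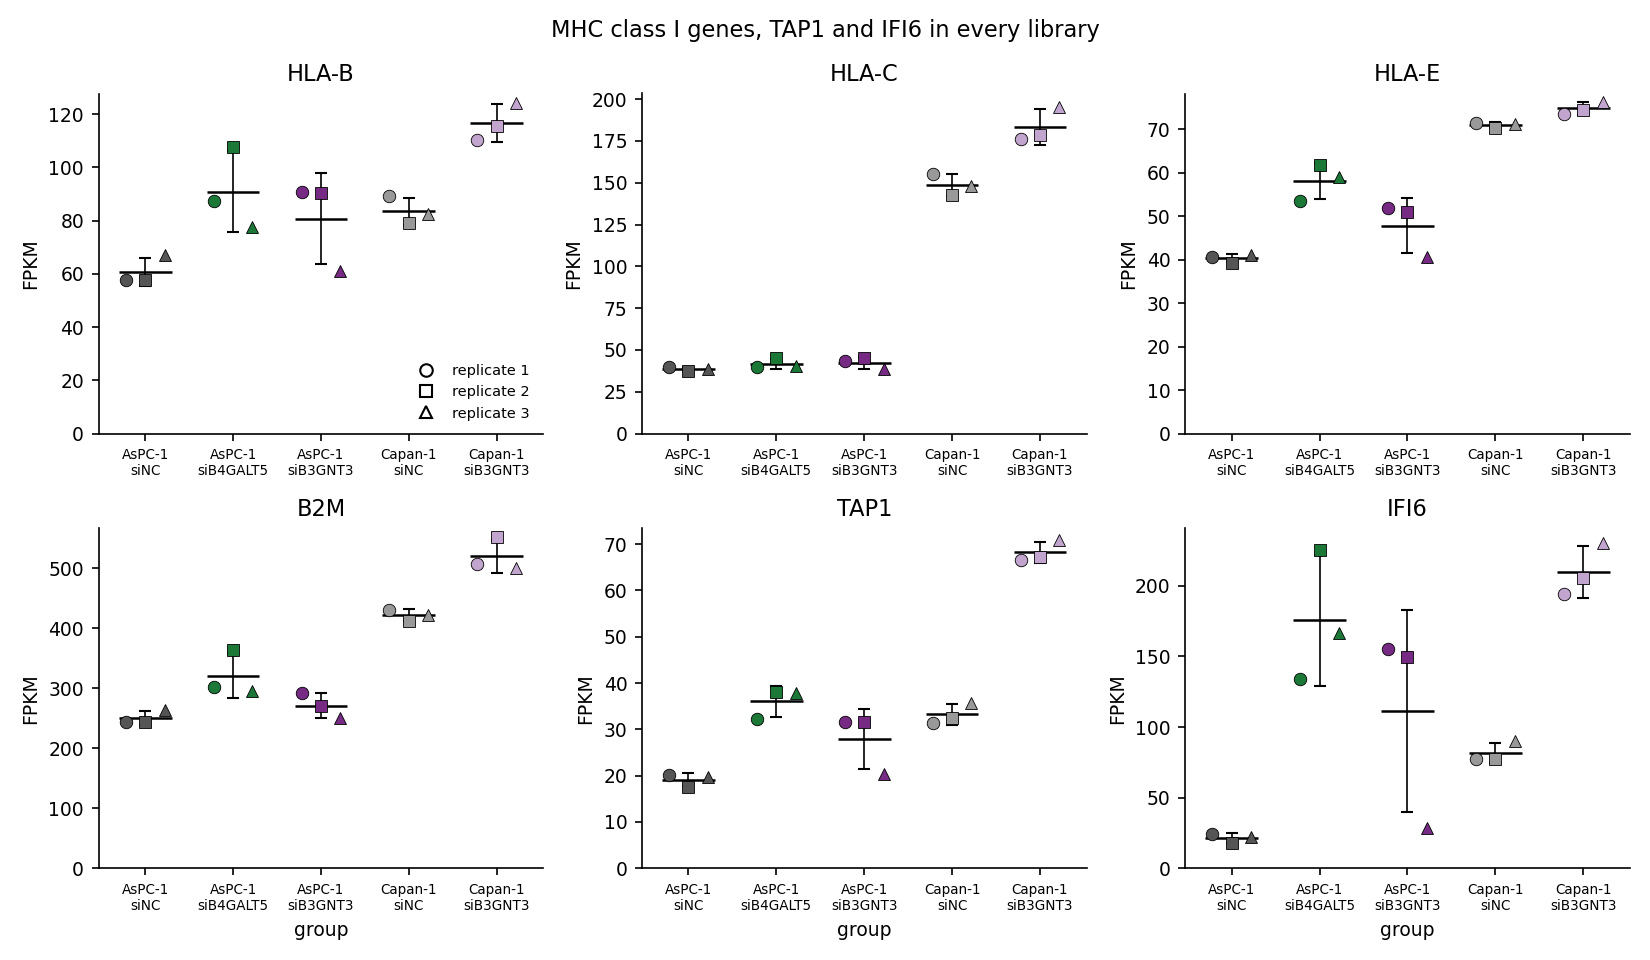
HLA-B, HLA-C, HLA-E, B2M, TAP1 and IFI6 in FPKM in each library by group; points are libraries, horizontal lines group means and error bars 1 SD (n = 3). IFI6 averaged 21.4 FPKM in AsPC-1 siNC, 176 with siB4GALT5 and, in Capan-1, 81.7 with siNC and 210 with siB3GNT3.

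Knockdown of B3GNT3 in Capan-1 asked for the same response in a line whose 3 knockdown libraries all had low B3GNT3. Interferon-stimulated genes had the smallest camera p there, though histone and ATF4 genes had higher medians. MX2, an antiviral GTPase, went from 5.09 ± 1.27 to 20.5 ± 2.21 FPKM (mean ± SD, n = 3; log2 fold change 1.83, SE 0.15, adjusted p = 0.000186). SOCS1, which restrains interferon signalling, went from 6.70 ± 0.303 to 26.4 ± 3.38 FPKM (1.83, adjusted p = 5.72e-05). OAS2, IFI6 and IFIT3 rose by 1.52, 1.35 and 1.34. Of 44 interferon-stimulated genes 40 rose and 0 fell (median 0.95, camera adjusted p = 9.84e-21, and 0.482 with an estimated correlation). Among stress genes SESN2 went from 4.67 ± 0.428 to 27.9 ± 15.8 FPKM (2.17, adjusted p = 0.00505) and DDIT3 from 16.0 ± 1.19 to 71.7 ± 35.5 FPKM (1.95, adjusted p = 0.00501). CHAC1, TRIB3 and DDIT4 rose by 2.04, 1.89 and 1.80, and 19 of 21 ATF4 genes rose with 0 down (median 1.03, adjusted p = 1.15e-06, and 0.501 with an estimated correlation). These genes differed within the group: over siB3GNT3 replicates 1, 2 and 3, DDIT3 was 102, 79.9 and 32.7 FPKM, DDIT4 310, 237 and 89.6 FPKM and CHAC1 13.1, 10.6 and 3.59 FPKM. Replicate 3 lay at root mean square log2 differences of 0.314 and 0.272 from replicates 1 and 2, which differed by 0.177. All 10 histone genes tested rose, H4C8 by 1.37 and H2BC5 by 1.24 (median 1.21, adjusted p = 1.87e-06, and 0.344 with an estimated correlation). H1-3, another histone gene, rose by 2.04 from 0.622 ± 0.415 FPKM (adjusted p = 0.00547).

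MHC class I mRNA rose in some chains. HLA-B went from 83.6 ± 5.07 to 117 ± 7.14 FPKM (mean ± SD, n = 3; 0.48, SE 0.07, adjusted p = 0.00243), HLA-C from 149 ± 6.35 to 183 ± 10.7 FPKM (0.30, adjusted p = 0.0109), and B2M from 422 ± 9.69 to 520 ± 27.6 FPKM (0.30, adjusted p = 0.00777). HLA-C lost its call without siNC replicate 2 or siNC replicate 3 (adjusted p = 0.0593 and 0.052). HLA-E and HLA-F had log2 fold changes of 0.08 and 0.09 (adjusted p = 0.316 and 0.461). The list had 3 of 6 up (median 0.20, camera adjusted p = 0.0782), and passed without siNC replicate 1 (0.24, adjusted p = 0.0467, and 0.512 with an estimated correlation). The processing list passed, with 10 of 15 up and 1 down (median 0.37, adjusted p = 0.0066, and 0.482 with an estimated correlation). TAP1 went from 33.2 ± 2.24 to 68.2 ± 2.27 FPKM (1.02, adjusted p = 9.88e-05), and PSMB8, NLRC5 and PSME1 rose by 0.60, 0.77 and 0.41. Of 7 MHC class II genes 3 rose and 0 fell, HLA-DRA by 0.64 (median 0.14, adjusted p = 0.0876). Genes of MHC class I turnover had 3 of 14 up and 3 down, MAP1LC3B rising by 0.45 and the protease SPPL3 falling by 0.45 (median 0.06, mean -0.01, adjusted p = 0.976). Ligands of T and NK cells had 10 of 20 up and 2 down, IDO1 rising by 1.10 and ULBP2 falling by 0.55 (median 0.29, adjusted p = 0.0538).

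Inflammatory genes rose in part. IL6 went from 19.7 ± 0.903 to 64.2 ± 20.7 FPKM (mean ± SD, n = 3; 1.60, SE 0.21, adjusted p = 0.00134), and CXCL2 and CXCL8 rose by 1.31 and 0.84 among 6 of 20 chemokines and cytokines (median 0.12, camera adjusted p = 0.0876). Of 15 NF-kB targets 9 rose and 1 fell, BCL3 rising by 1.30 and BIRC3 by 1.04 (median 0.47, adjusted p = 0.00972, and 0.552 with an estimated correlation). Other genes fell. TMA7 went from 124 ± 4.49 to 25.5 ± 5.44 FPKM (-2.26, adjusted p = 7.98e-05), and the zinc transporter SLC39A1 from 120.3 ± 2.6 to 29.1 ± 1.04 FPKM (-2.01, adjusted p = 4.03e-06). SLBP, which binds histone mRNA, went from 43.9 ± 1.22 to 10.7 ± 3.26 FPKM (-1.97, adjusted p = 0.000214). FGFBP1, NDUFA12 and SLC39A14 fell by 2.00, 1.96 and 1.85. HSPA1A, which shares reads with a near-identical copy, fell by 2.21.

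Of 34 cell cycle genes 17 fell and 0 rose in Capan-1, CCNE1 by 1.14 and MKI67 by 0.80 (median -0.25, camera adjusted p = 4.84e-07, and 0.552 with an estimated correlation). ER chaperone genes had 10 of 22 down and 2 up, PDIA6 falling by 0.73 and CALR by 0.42 (median -0.22, adjusted p = 0.00907, and 0.482 with an estimated correlation). Basal-like genes had 7 of 15 down and 1 up, KRT17 falling by 1.22 and S100A2 by 1.01 (median -0.30, adjusted p = 0.0103, and 0.482 with an estimated correlation). Cholesterol synthesis had 5 of 23 down and 1 up, MVD falling by 0.76 (median -0.16, adjusted p = 0.0289, and 0.501 with an estimated correlation). Hypoxia and glycolysis had 9 of 29 down and 5 up, PFKFB3 falling by 0.95 and ADM rising by 1.08 (median -0.25, adjusted p = 0.0327, and 0.632 with an estimated correlation). Mesenchymal genes had 8 of 21 up and 1 down, FN1 rising by 0.94 (median 0.19, adjusted p = 0.0538). EGFR and MAPK output had 5 of 21 up and 2 down, FOSL1 falling by 1.06 (median 0.45, adjusted p = 0.18). In the families of both targets 3 of 14 fell, B3GNT3 and B4GAT1 among them, and 1 rose: B4GALT1 went from 15.2 ± 0.254 to 25.8 ± 3.21 FPKM (0.72, adjusted p = 0.00109; list median -0.11, adjusted p = 0.0876).

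The other lists had no call in Capan-1. O-glycan synthesis had 5 of 17 down and 2 up (median -0.15, camera adjusted p = 0.11), and classical genes 5 of 14 down and 2 up, ANXA10 falling by 1.00 and GATA6 rising by 0.81 (-0.12, adjusted p = 0.195). Lysosome genes had 10 of 36 up and 3 down (0.08, adjusted p = 0.246), YAP targets 4 of 15 up and 2 down (0.14, adjusted p = 0.489), and epithelial genes 5 of 17 up and 6 down (-0.08, adjusted p = 0.626). Ribosomal protein genes had 5 of 34 down (-0.05, adjusted p = 0.0538), mitochondrially encoded mRNAs 2 of 13 down (-0.09, adjusted p = 0.114), and leukocyte markers 1 of 3 up and 1 down, CD14 rising and LYZ falling (0.21, adjusted p = 0.658). The medians of another 4 lists changed sign with the scaling: 6 of 21 glycosphingolipid genes changed (adjusted p = 0.356), 2 of 5 mucins, MUC16 rising by 0.58 and MUC13 falling by 0.57 (0.976), 11 of 16 p53 targets (0.626) and 3 of 4 fibroblast markers (0.976). Endothelial markers and acinar and endocrine markers had fewer than 3 genes past the expression filter in either line and were not tested.

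In total 3786 of 11493 genes changed with B3GNT3 knockdown in Capan-1, 2152 up and 1634 down, and 209 at least 2-fold (121 up, 88 down). In each gene named here as changed, the 3 knockdown libraries lay beyond the 3 controls, as the naming rule required for the largest changes. The up calls numbered 1784 and the down calls 2079 with median-ratio scaling, and 2546 and 1416 with rescaling to a common sum. Adjusted over the list alone, the counts differed in 11 lists: 41 interferon-stimulated genes, 12 ligands of T and NK cells, 9 genes of EGFR and MAPK output, 4 of MHC class I turnover, 3 basal-like genes and 2 leukocyte markers rose, and 12 ER chaperone, 6 O-glycan, 2 processing, 2 fibroblast and 2 ribosomal protein genes fell. The count of changed genes was 2069, 2083 and 2112 without siNC replicates 1, 2 and 3, and 5715 of 11338 without siB3GNT3 replicate 3. Without the latter, 4 lists gained a call: EGFR and MAPK output (adjusted p = 0.000916), mesenchymal genes (0.0182), ligands of T and NK cells (0.0396) and the families of both targets (0.0396). With an estimated correlation none of these was called (0.422 for each), and the list of both families holds the target B3GNT3. With median-ratio scaling ligands of T and NK cells, mesenchymal genes and ribosomal protein genes gained a call (0.0393, 0.047 and 0.0202, and 0.442, 0.48 and 0.612 with an estimated correlation). Simulated changes in this comparison were drawn with the spread of the siNC libraries. Of 67 genes with 1.5-fold changes 61 were recovered, with 16 false calls among 11353 genes tested.

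The siB4GALT5 and siB3GNT3 groups in AsPC-1 were also compared with each other, to find genes that differ between the siRNAs. The siRNAs differ in sequence as well as in target, so an effect of the enzyme cannot be told from one of the sequence. B4GALT5 was lower with siB4GALT5, 8.41 ± 0.343 against 35.0 ± 1.62 FPKM (mean ± SD, n = 3; log2 fold change -1.94, SE 0.07, adjusted p = 2.35e-06). B3GNT3 was higher, 30.3 ± 2.29 against 9.73 ± 12.5 FPKM (2.21, adjusted p = 0.0435). EBPL, LMAN2, GCSH and DPYSL2 were lower with siB4GALT5 by log2 fold changes of -2.69, -2.50, -2.16 and -1.78 (adjusted p = 2.45e-05, 2.35e-06, 2e-05 and 2e-05). IGFBP4, which binds insulin-like growth factors, was higher, 48.9 ± 6.99 against 11.6 ± 9.05 FPKM (2.20, adjusted p = 0.00634). The water channel AQP1 and the protease FURIN were higher by 1.78 and 1.64 (adjusted p = 0.0114 and 0.00353), and EEF1A1 by 1.91 (adjusted p = 0.0469). The NF-kB regulator TNIP1 was higher by 1.21 and the YAP target CCN1 by 1.13, and the T cell ligand HHLA2 lower by -1.06. The calls of B3GNT3 and EEF1A1 ended without any single library but the one labelled AsPC-1 siB3GNT3 replicate 3 (adjusted p = 0.0717 to 0.128 over those 8 libraries) and with median-ratio scaling (0.051 and 0.0564). HLA-F was lower with siB4GALT5 (-0.52, adjusted p = 0.0239), a call lost without siB4GALT5 replicate 1 or 2 or siB3GNT3 replicate 1 or 2 (adjusted p = 0.0891, 0.0808, 0.076 and 0.0664). HLA-B, HLA-C, HLA-E and B2M had log2 fold changes of 0.18, -0.01, 0.28 and 0.24 (adjusted p = 0.499, 0.926, 0.089 and 0.113).

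Interferon-stimulated genes were higher with siB4GALT5 than with siB3GNT3, 5 of 39 single genes and 22 adjusted over the list alone, STAT2 and OAS3 among them (median 0.78, camera adjusted p = 1.56e-05, and 0.971 with an estimated correlation). Without the library labelled AsPC-1 siB3GNT3 replicate 3 the median was 0.36 (adjusted p = 0.000696, and 0.639 with an estimated correlation). Another 4 lists were called only with that library in the group: mesenchymal genes, with PLAUR and ITGA5 higher by 0.78 and 0.71 (adjusted p = 0.046, and 0.635 with an estimated correlation), classical genes, with HNF4A and TSPAN8 lower (0.046, and 0.635), cell cycle genes (0.046, and 0.971) and mitochondrially encoded mRNAs (0.046, and 0.971). With median-ratio scaling these 4 calls ended (0.107, 0.0522, 0.0919 and 0.0919), and with rescaling to a common sum all but that of classical genes (0.173, 0.0617 and 0.0617). In total 1716 of 10804 genes differed, 894 higher and 822 lower with siB4GALT5. The count was 1142 without siNC replicate 3, 733 and 786 without siB4GALT5 replicates 1 and 2, 1010 without siB3GNT3 replicate 1, and 3789 without the library labelled AsPC-1 siB3GNT3 replicate 3. A fit of only the 6 libraries compared called 534.

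The response to B3GNT3 knockdown was compared between the lines as AsPC-1 minus Capan-1, with directions in AsPC-1 drawn from a group that holds the library labelled AsPC-1 siB3GNT3 replicate 3. The sources used here do not say whether both lines received the same siRNA. A difference between lines may thus be one between siRNA sequences. A higher response in AsPC-1 means a positive difference, which a fall in Capan-1 alone can also give. KRT17 averaged 6.93 ± 0.842 FPKM with siNC and 32.0 ± 21.7 with siB3GNT3 in AsPC-1, and 20.9 ± 2.5 and 8.41 ± 1.16 in Capan-1 (SD, n = 3; difference 2.91, SE 0.65, adjusted p = 0.0129). The zinc transporter SLC39A14 was 29.7 ± 1.4 and 36.5 ± 5.75 FPKM in AsPC-1 and 37.1 ± 1.9 and 9.61 ± 1.66 in Capan-1 (2.13, adjusted p = 2.32e-05). PPP1R14B and HSPA1A had positive differences too (2.12 and 1.98, adjusted p = 0.00144 and 0.0137), and HSPA1A fell in Capan-1. SOCS1 was 2.16 ± 0.436 and 1.94 ± 0.158 FPKM in AsPC-1, against its rise in Capan-1 (-1.93, adjusted p = 3.26e-05), and SOCS3 behaved alike (-1.60, adjusted p = 0.000105). Several differences concerned genes hardly expressed in AsPC-1 under either siRNA: there IL6 averaged 0.00551 and 0.0538 FPKM (-1.54, adjusted p = 0.00154), CYP24A1 0.0279 and 0.00404 FPKM (-1.83, adjusted p = 9.18e-05), H1-3 0.120 and 0.482 FPKM (-1.69, adjusted p = 0.0372) and GPX2 0.156 and 0.649 FPKM (1.93, adjusted p = 0.00164). H1-3 lost its call without 10 of the libraries left out in turn: the 3 AsPC-1 siNC libraries (adjusted p = 0.0673, 0.0697 and 0.0864), siB4GALT5 replicates 1 and 2 (0.0504 and 0.051), AsPC-1 siB3GNT3 replicate 2 (0.0735), Capan-1 siNC replicates 2 and 3 (0.0738 and 0.0969) and Capan-1 siB3GNT3 replicates 1 and 2 (0.0798 and 0.0859). With a pseudocount of 0.1, H1-3 and IL6 were not called (adjusted p = 0.23 and 0.0973), and H1-3 was not called with rescaling to a common sum (0.0794).

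In the interaction of line and knockdown, 0 of the 6 MHC class I chains differed by limma (lowest adjusted p = 0.311, for HLA-C, at -0.18). Without the library labelled AsPC-1 siB3GNT3 replicate 3, HLA-E differed (0.27, adjusted p = 0.0216). So did IFI27, EEF1A1 and RDH11 (3.31, -2.10 and -1.87, adjusted p = 0.000115, 9.33e-08 and 6.42e-07). CTDSP1, a phosphatase, differed without that library (-1.88, adjusted p = 0.000939) and without Capan-1 siB3GNT3 replicate 3 (-1.68, adjusted p = 0.0473). ER chaperone genes responded higher in AsPC-1, 7 of 22 with 0 lower, PDIA6 by 0.57 and CALR by 0.41 (median 0.36, camera adjusted p = 0.000746, and 0.366 with an estimated correlation; 10 adjusted over the list alone). Mesenchymal genes responded lower, 5 of 22 with 0 higher, FN1 and ZEB1 among them (-0.20, adjusted p = 0.0146, and 0.396 with an estimated correlation; without that library 0.0915). Without that library cholesterol synthesis and mitochondrially encoded mRNAs also responded lower in AsPC-1 (median -0.43 and -0.23, adjusted p = 9.77e-06 and 0.00385, and 0.176 and 0.655 with an estimated correlation). With rescaling to a common sum and all libraries, MHC class II, basal-like, cholesterol and ribosomal protein genes gained a call (adjusted p = 0.0254, 0.0314, 0.0345 and 0.0314, and 0.163, 0.163, 0.994 and 0.994 with an estimated correlation). Interferon-stimulated genes had a median of -0.13 with 5 of 44 lower (adjusted p = 0.135), and 0.32 without that library (0.165). Among these 5 were MX1, MX2 and TRIM22, under 1 FPKM with siNC and siB3GNT3 in AsPC-1, and STAT2, which was 6.08 ± 0.604 and 6.33 ± 0.19 FPKM there (SD, n = 3; -0.51, adjusted p = 0.0287).

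In total 1204 of 12247 genes differed between the lines in their response, 661 higher and 543 lower in AsPC-1. Left out in turn, the AsPC-1 siNC libraries gave 712, 736 and 775, AsPC-1 siB3GNT3 replicates 1 and 2 763 and 794, the Capan-1 siNC libraries 778, 793 and 775, and Capan-1 siB3GNT3 replicate 3 2030. Without the library labelled AsPC-1 siB3GNT3 replicate 3, 4009 genes differed.

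Both knockdowns in AsPC-1 changed many of the same genes. Across 10804 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.704, against 0.50 for simulated unchanged groups that share the 3 siNC libraries. The covariance was 0.101 against 0.0131 in the simulation. Without the library labelled AsPC-1 siB3GNT3 replicate 3, r was 0.704 against 0.449. Then 2584 genes rose in both, where independent lists would share 1234, and 1306 fell in both, where they would share 504.1; 305 moved in opposite directions. Part of this excess may come from the shared controls, since 3 control libraries cannot be split. The lines share no controls, and the response to B3GNT3 knockdown had an r of 0.414 across 10085 genes between them. Without that library 1052 genes rose in both lines, against 570.6 for independent lists, 586 fell, against 317.1, and 382 moved in opposite directions.

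**Figure D4:**
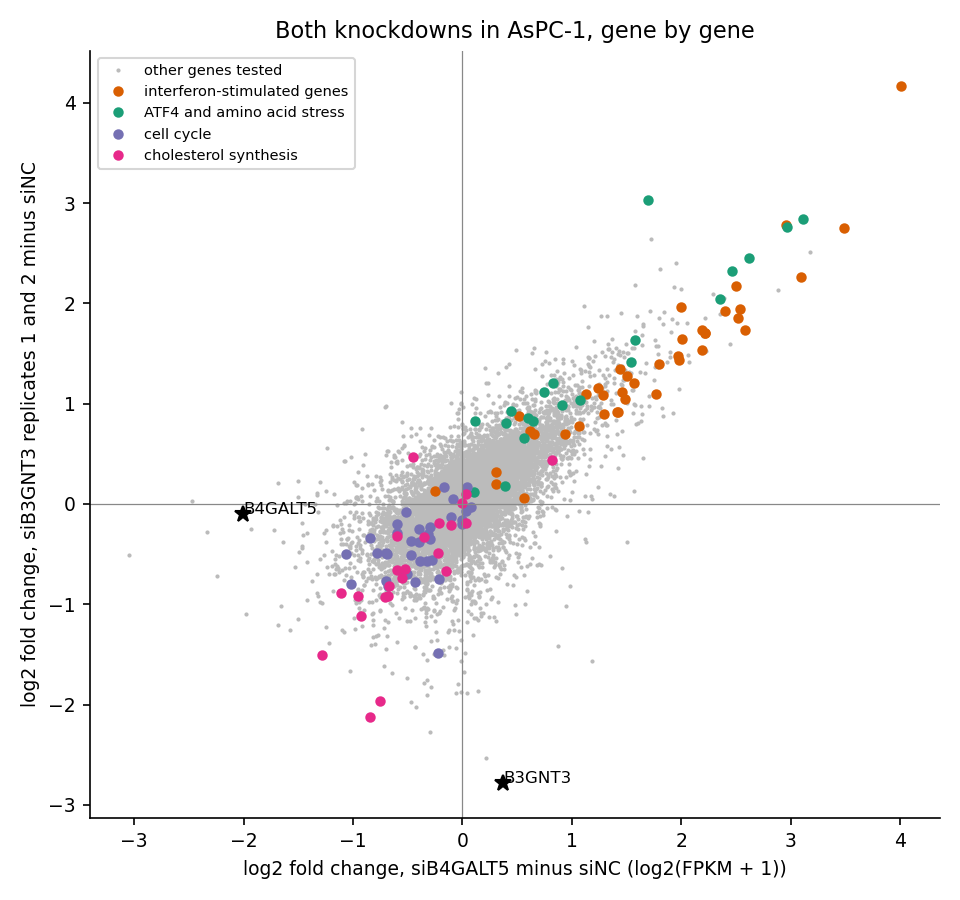
Log2 fold change of each gene tested (log2(FPKM + 1)) with siB4GALT5 against siNC and with siB3GNT3 replicates 1 and 2 against siNC in AsPC-1, with 4 gene lists and both targets marked. The values had a Pearson r of 0.704 across genes, against 0.449 for simulated unchanged groups that share the controls.

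Across all 3 knockdowns, without the library labelled AsPC-1 siB3GNT3 replicate 3, 861 of 10068 genes rose in each and 387 fell in each. Of these 35 rose at least 2-fold in each, SESN2, DDIT3, TRIB3 and OAS2 among them, and 0 fell at least 2-fold in each. Interferon-stimulated genes rose in all 3 for 33 of 39 tested, ATF4 genes for 15 of 18 and histone genes for 5 of 9, and 13 of 34 cell cycle genes fell in all 3. Of the MHC class I chains 1 of 6 rose in all 3, HLA-B, and of the processing genes 4 of 15.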

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

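The interaction tests, scalings and splits were planned, while the tests on the wrong label, the swap, the copied control, the lists without the library labelled AsPC-1 siB3GNT3 replicate 3, the low AsPC-1 controls, the siRNA duplexes and the other knockdown libraries taken alone were chosen only after the result was seen. The seed tests were added once the falls and the odd libraries had been seen, with their bounds set before the scores were computed.

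The library labelled AsPC-1 siB3GNT3 replicate 3 had B3GNT3 at the level of the controls and may carry a wrong label. A swap within the line is argued against, since the lowest B3GNT3 among the 6 libraries of the other AsPC-1 groups was 22.5 FPKM. A copy of one of the 3 deposited controls is argued against too, as its smallest distance from a control was 0.987 of the smallest between controls. An siRNA that acted on other transcripts but not on its target is argued against by a score of 0.343 for the 7-mer of replicates 1 and 2. A wrong label, such as a further control library under this name, and cells in which no siRNA acted cannot be told apart: 0 genes differed from the controls, where the same test called 4094 to 5841 in each other AsPC-1 knockdown library, and either would give that.

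Interferon-stimulated genes rose in all 3 knockdowns, though for B3GNT3 in AsPC-1 single genes passed over all genes only without the library labelled AsPC-1 siB3GNT3 replicate 3, while the list passed with it too (camera adjusted p = 1.01e-09, but 0.561 with an estimated correlation). Scaling does not account for it, as the lowest list median under median-ratio scaling was 0.80, for siB3GNT3 in AsPC-1 with all libraries. Without the library labelled AsPC-1 siB3GNT3 replicate 3 the lowest was 0.90, in Capan-1. Low values in the AsPC-1 controls cannot give the rise in Capan-1, which has its own controls (median 0.95). Whether they add to the rises in AsPC-1 stays open, since both knockdowns there share those controls. The rise may be a response to the targeting siRNA duplexes, beyond that to siNC, rather than to loss of either enzyme: 33 members rose in all 3 comparisons, as either would give. A second control siRNA or a rescue with the enzyme would separate these, and neither is among the libraries.

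Genes that fell may include off-targets of the siRNAs through seed matches. The lowest-scoring 7-mer was GAGAACA at -9.777 with siB4GALT5, TGTGCCA at -12.56 with siB3GNT3 in AsPC-1 (both scored without the library labelled AsPC-1 siB3GNT3 replicate 3) and TGGAGCT at -16.76 with siB3GNT3 in Capan-1, against a Bonferroni bound of -4.52. Each occurs in the mRNA of its target, as do 22.9% of all 7-mers for B4GALT5 and 11.9% for B3GNT3, and 7, 10 and 5 other 7-mers passed the bound in the opposite direction. Of genes that fell at least 2-fold, 32.0%, 42.5% and 59.3% held the 7-mer in these comparisons, against 13.9%, 19.2% and 15.2% of the other genes. The same changes picked each 7-mer, so these shares describe the falls and are no independent test. Each 7-mer also scored lowest in every library of its group, except the library labelled AsPC-1 siB3GNT3 replicate 3. Another siRNA in Capan-1 siB3GNT3 replicate 3, which stood apart from replicates 1 and 2, is argued against by its score of -15.14 for their 7-mer. The siRNA sequences are not given in the sources used here, so the lines may have received different ones, as TGGAGCT scored -2.38 in AsPC-1.

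The response to B3GNT3 knockdown differed between the lines in 1204 genes. The lines may have received different siRNAs, so a difference between lines cannot be told from one between siRNA sequences. ER chaperone genes differed as a list (camera adjusted p = 0.000746, and 0.366 with an estimated correlation). Mesenchymal genes did too (0.0146, and 0.396 with an estimated correlation), but not without the library labelled AsPC-1 siB3GNT3 replicate 3 (0.0915). Genes with a positive difference, AsPC-1 minus Capan-1, were KRT17 (2.91), SLC39A14 (2.13), PPP1R14B (2.12), HSPA1A (1.98), GPX2 (1.93), TMA7 (1.91), NDUFA12 (1.83), SLBP (1.61), FGFBP1 (1.44), ANXA10 (1.04), S100A2 (0.97), PFKFB3 (0.92), ULBP2 (0.83), HSPA5 (0.76), MUC13 (0.75), PDIA6 (0.57), SPPL3 (0.49), LYZ (0.46) and CALR (0.41). A fall in Capan-1 alone can give such a value. SLC39A14, HSPA1A, TMA7, NDUFA12, SLBP, FGFBP1, S100A2, PFKFB3, ULBP2, MUC13, PDIA6, SPPL3 and CALR fell there. TMA7 had log2 fold changes of -0.554 in AsPC-1 siB3GNT3 replicates 1 and 2 and -2.26 in Capan-1. Genes with a lower response in AsPC-1 were SOCS1 (-1.93), CYP24A1 (-1.83), H1-3 (-1.69), SOCS3 (-1.60), IL6 (-1.54), MX2 (-1.36), MX1 (-1.35), FN1 (-1.25), ADM (-1.19), IDO1 (-1.08), ZEB1 (-1.02), BCL3 (-1.01), TRIM22 (-0.96), CD14 (-0.65), NLRC5 (-0.63), MUC16 (-0.57) and HLA-DRA (-0.57). Of all these ANXA10, CD14, CYP24A1, FN1, GPX2, H1-3, HLA-DRA, IDO1, IL6, LYZ, MUC16, MX1, MX2 and TRIM22 averaged under 1 FPKM in AsPC-1 with both siNC and siB3GNT3, so their values mostly reflect the change in Capan-1. Groups of 3 libraries are too small for an outlier test.

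Counts of changed genes were set against other splits of the same libraries into groups. With 10 splits of 6 libraries no share under 0.05 is possible: the real split of siB4GALT5 and siNC gave 4239 and the highest other 0, so 1 split reached it. For siB3GNT3 in AsPC-1 the real split and the highest other gave 0, so 10 did. In Capan-1 the real split gave 3786 and the highest other 0, and between both knockdowns 1716 and 1, so 1 split reached each. For the interaction 5 of 100 splits gave at least 1204, but all 5 kept the Capan-1 groups whole and so carried the change there, while splits that mixed these groups gave at most 1. They are no reference without change, and whether chance gives that count stays open. The highest other gave 4207, a structure of the libraries rather than of the groups, from a split that set siB3GNT3 replicates 1 and 2 with a control against the library labelled AsPC-1 siB3GNT3 replicate 3.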

How the results depend on the processing

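Most alternatives were planned, while the tests without the 13 mitochondrially encoded mRNAs, of agreement with each library left out, of lists, named genes and agreement without the library labelled AsPC-1 siB3GNT3 replicate 3, and of lists without Capan-1 siB3GNT3 replicate 3 and under the other scalings, and of MHC class I lists under the alternatives with an estimated correlation, were chosen only after the result was seen. Of 1444 values for 106 results, each a named gene in a comparison, 1356 stayed as they were, called or not, while 57 lost a call, 31 gained one and 0 reversed. For siB3GNT3 in AsPC-1, 22 of these results were uncalled with all libraries. Of them 21 gained a call without the library labelled AsPC-1 siB3GNT3 replicate 3, and 0 changed under any other alternative. Their unchanged values thus say little of how stable calls are.

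With single libraries left out in turn, the counts ranged from 2439 to 6271 for siB4GALT5 in AsPC-1, 0 to 5697 for siB3GNT3 in AsPC-1, 2069 to 5715 in Capan-1, 733 to 3789 between both knockdowns and 712 to 4009 for the interaction; the highest came without the library labelled AsPC-1 siB3GNT3 replicate 3, and in Capan-1 without siB3GNT3 replicate 3. Target fold changes ranged from -2.02 to -1.96 for B4GALT5, -2.78 to -1.36 for B3GNT3 in AsPC-1 and -2.53 to -2.39 in Capan-1. The list median of interferon-stimulated genes ranged from 1.45 to 1.70, 0.63 to 1.27 and 0.88 to 1.04 in the 3 knockdowns, of MHC class I chains from 0.34 to 0.48, 0.17 to 0.34 and 0.16 to 0.24, and of processing genes from 0.11 to 0.16, 0.09 to 0.22 and 0.29 to 0.38. Agreement ranged from 0.678 to 0.712 between the knockdowns in AsPC-1 and from 0.383 to 0.438 between lines. For siB3GNT3 in AsPC-1, simulated changes gave 0 calls when placed in replicates 1 and 2 only and 7646 when placed in all 3. The cause of the other shifts was not tested.

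An added threshold of 2-fold left 434, 0, 209, 113 and 169 genes in the 5 comparisons, which follows from the threshold. With no filter 3 genes were called for siB3GNT3 in AsPC-1, and MHC class I chains passed there (median 0.23, camera adjusted p = 0.0279) and in Capan-1 (0.10, adjusted p = 0.013), but not with an estimated correlation (0.614 and 0.445). In a fit of all 15 libraries these chains also passed for siB3GNT3 in AsPC-1 (camera adjusted p = 0.0457, and 0.662 with an estimated correlation). Median-ratio scaling called 1 gene for siB3GNT3 in AsPC-1, and a fit of only the groups compared called 534 between both knockdowns. With an estimated correlation the medians stayed at 1.57, 0.86 and 0.95 for interferon-stimulated genes and 0.37 for processing genes in Capan-1, but no list was called (adjusted p = 0.52, 0.561, 0.482 and 0.482). Among genes called in at least one comparison agreement was 0.823 and 0.531. Without mitochondrially encoded mRNAs 4085 and 3809 genes changed with siB4GALT5 in AsPC-1 and siB3GNT3 in Capan-1.

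With the replicate number as a block (replicate block) the counts were 3986, 0, 3311, 1383 and 923, and between both knockdowns HLA-F, B3GNT3 and EEF1A1 lost their calls (adjusted p = 0.0518, 0.0522 and 0.0523). Correlations of residuals between replicates with the same number did not all exceed 0.1 in any comparison: they were 0.0307, 0.0599 and 0.0261 for siB4GALT5 and siNC, -0.0157, 0.05 and 0.0359 for siB3GNT3 and siNC in AsPC-1, -0.00545, 0.052 and -0.0351 in Capan-1, and -0.0367, 0.128 and 0.0684 between both knockdowns. Of 6 libraries each, 6, 4, 1 and 4 correlated best with the library of their own number. Read depth is unknown, so its part in calls of low genes could not be tested; the counts of 0 and 3 with and without the filter bear on it for siB3GNT3 in AsPC-1 only.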

Other observations

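The tests of overlap described here were planned for the pairs that share a knockdown or a line, while the test of B4GALT5 in AsPC-1 against B3GNT3 in Capan-1 and those without the library labelled AsPC-1 siB3GNT3 replicate 3 were chosen only after the result was seen.

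Stress and interferon genes were among the 35 genes that rose at least 2-fold in all 3 knockdowns, with AsPC-1 siB3GNT3 taken from replicates 1 and 2. GDF15 rose by 1.69, 3.03 and 1.65, ATF3 by 2.46, 2.32 and 1.60 and CEBPB by 1.57, 1.64 and 1.42 in siB4GALT5, siB3GNT3 in AsPC-1 and siB3GNT3 in Capan-1; these genes were picked from the 35 after their values were seen. ISG15 and IRF7 rose with them (2.22, 1.71 and 1.02; 2.00, 1.65 and 1.27).

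B4GALT5 knockdown in AsPC-1 and B3GNT3 knockdown in Capan-1 share neither target, line nor controls. Their log2 fold changes had a Pearson r of 0.347 across 10068 genes, which are not independent replicates, with 1035 genes up in both (623.7 for independent lists), 548 down in both (355.4) and 522 opposite. A response to the targeting siRNA duplexes beyond that to siNC may underlie part of it, which was not tested. The 33 interferon-stimulated genes that rose in all 3 knockdowns do not tell this from an effect of losing the enzymes.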
